A study of Homo sapiens with 12 samples.

How the data were processed

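Total RNA from PANC-1 cells, extracted with Trizol per the labels, was biotin-labelled with the Illumina TotalPrep kit and hybridised to Illumina BeadChip arrays. The deposited table of non-normalized values gives, for each of 47231 probes and 12 arrays, a bead signal intensity on a linear scale that was not normalized between arrays. The same deposited table gives a detection p-value of each probe on each array, where a low value means signal above the background. The deposited scaled values are also a signal intensity on a linear scale, and each array's values equal its non-normalized values multiplied by 1 constant, from 0.926 to 1.12 over the 12 arrays. The scanning and summarising software and their versions are not given in the sources used here, nor are the slides on which the arrays lay.

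The non-normalized values were analysed in R 4.3.3 with limma 3.58.1. Neqc estimated the background of each array from the detection p-values, added an offset of 16, normalized the arrays to common quantiles and took log2. A probe was kept when its detection p was under 0.05 in at least 3 arrays, which left 21195 probes. Gene symbols came from the probe annotation supplied for the array: 30113 probes have 1 symbol, 8 have several and 17110 have none. The probe with the highest mean was taken for each symbol, and probes without a single symbol were kept as features of their own, giving 17369 features, 11725 with a symbol and 5644 without. Values named as the other probe of a gene come from its remaining detected probes.

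A linear model with the 4 group means and moderated variances (limma lmFit and eBayes) tested premir miR-10b against premir control, antimir-10b against antimir control, the difference between these effects, and antimir control against premir control, two-sided. P-values were adjusted by Benjamini-Hochberg over all features of a comparison, and a feature was called at an adjusted p under 0.05. For each of 29 gene lists, camera with a preset correlation of 0.01 compared the list with all other features, adjusted over the lists, and the number of members called was also counted with p adjusted over the list alone. Beside it stand camera with an estimated correlation and fry, a rotation test of whether the genes of a list move on balance one way. The lists held named miR-10b targets, epithelial and mesenchymal state, invasion, EGF receptor, ERK and TGF-beta pathways, the cell cycle, p53, interferon, NF-kB, lipid, stress and hypoxia responses, metallothioneins, HOX genes, small RNA machinery, histones, ribosome, mitochondria, apoptosis, and markers of fibroblasts, leukocytes, endothelium, acinar and islet cells and ducts. A fold against a group in which a gene was not detected is given as at least the fold to the detection limit of the arrays.

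The groups, comparisons, tests, lists, the rule for named genes and the alternatives were chosen before the data were examined, except where an analysis is described as chosen later. For each main comparison the rule names up to 12 called genes with the largest rise and 12 with the largest fall whose treated arrays all lie beyond the control arrays (which 10% of genes would show by chance with 3 arrays against 3), or the 5 genes with the smallest p in a direction with fewer than 5 calls. With 2 premir miR-10b arrays, as in the 11-array analysis, more genes would show this by chance and the rule is less strict. It adds up to 2 called members in each direction of every list past the threshold, or the 2 with the smallest p where none is called, a fixed set of 17 genes, genes called in both main comparisons in opposite directions, and the 5 largest called rises and falls of the other comparisons. Genes known only by a locus identifier are counted but not named. The fit without premir miR-10b replicate 2, which kept the normalization of the 12 arrays and is called the 11-array analysis, was added after that array had been seen to stand apart. So were normalization of those 11 arrays alone and the comparisons with the 6 antimir-arm arrays.

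The other settings chosen in advance were the values scaled by the authors, median centring, normexp with an offset of 50, no background correction, no filter, detection at p under 0.01 in all arrays, every probe tested alone, the replicate number as a block, trended and robust variances, array weights, a fold minimum of 1.2, the compared arrays alone, and leaving out each array in turn. Matches of 3′ untranslated regions to the miR-10b seed were not analysed here, since no transcript sequences were available, and neither was a block by slide. On simulated data of 17369 features with the spread of these arrays, 50 features were changed at each of 1.5-, 2-, 3- and 4-fold. The 12-array analysis recovered 2%, 38%, 64% and 86% of them with 0 false calls among 17139 unchanged features. The 11-array analysis recovered 44%, 96%, 100% and 100% with 9 false calls. Camera gave a p of 3.76e-08 and 1.77e-12 for a shifted list and 0.967 and 0.652 for an unshifted list. The simulated noise was drawn separately for each feature, so these p-values do not test the preset correlation of 0.01 on lists whose members vary together.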

Results

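PANC-1, a human cell line from a pancreatic ductal adenocarcinoma, was profiled on Illumina BeadChip arrays 20 h after transfection of 1 of 4 small RNA oligos. The premir miR-10b oligo is a synthetic precursor that adds the microRNA miR-10b, and antimir-10b is an inhibitor directed at it. Each has its own control oligo, and each of the 4 groups holds 3 biological replicates on 3 arrays, 12 arrays in all. The arrays read 47231 probes, of which 30113 carry 1 gene symbol. In 11 arrays the median raw signal lay between 64.5 and 76.3 and 39.2% to 41.3% of probes were detected. Premir miR-10b replicate 2 stood apart, with 29.5% of probes detected and a median correlation of 0.860 with the other arrays, where the lowest correlation among the other 11 arrays was 0.983. The 95th percentile of its raw signal was 733.1, against 1188.2 to 1778.3 on the other arrays, while its median raw signal of 64 lay just under their range. Its 3 probes for beta-actin (ACTB) read 205.9, 1504.4 and 3398.4, against 10515.5 to 20144.2 on the other arrays. The number of arrays limits the precision of every value. Positions are not given, since no genome build is named in the sources used here.

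**Figure D1:**
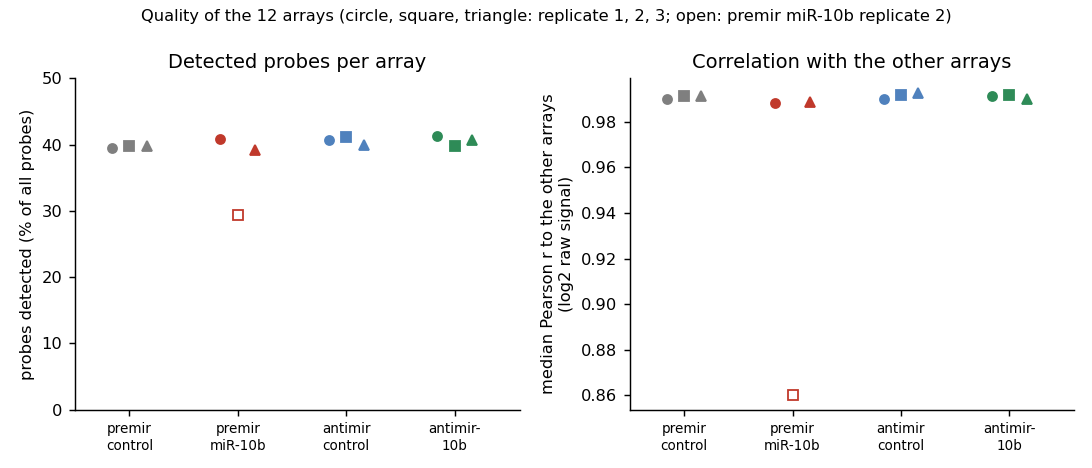
The left panel plots the percentage of probes detected on each of the 12 arrays, by group. The right panel plots the median Pearson correlation of each array's log2 raw signal with the other arrays, leaving premir miR-10b replicate 2 out of those others. Premir miR-10b replicate 2 (open square) lies at 29.5% detected and a correlation of 0.860, while the other 11 arrays lie between 39.2% and 41.3%.

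The comparison of premir miR-10b with premir control asks which transcripts change when miR-10b is added. HTATIP2 (also called TIP30), a tumor suppressor known as a miR-10b target in pancreatic cancer cells, fell 2.25-fold, from a normalized log2 signal of 10.99 ± 0.08 (SD, n = 3) to 9.82 ± 0.20 (SD, n = 3), with a log2 change of -1.17 ± 0.13 (SE) and a limma adjusted p of 0.0137. CDK6, a kinase that drives cells out of G1, fell 2.18-fold, and SKA1, a component of the kinetochore, had a log2 change of -1.37. KRT80, an epithelial keratin, rose 3.18-fold, and AXL, a receptor tyrosine kinase, rose 6.91-fold, or 4.43-fold without premir miR-10b replicate 2. The AXL call was lost in 16 of 24 alternatives with 12 arrays, and AXL was not higher than in the antimir arm (log2 difference -0.26 with 11 arrays). With all 12 arrays limma called 22 of 17369 features, 8 of them higher and 14 lower, and 1 of the 22 has no symbol. With the 11 arrays that exclude premir miR-10b replicate 2, an analysis added after that array had been seen, 124 features were called, 40 higher and 84 lower. All 14 features that fell and all 8 that rose with 12 arrays were called the same way with 11.

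The other genes that fell with 12 arrays included CRLF3, a cytokine receptor-like factor, with a log2 change of -2.49 ± 0.35 (SE) at the main probe and -1.10 at its other probe. CMPK1, a nucleoside monophosphate kinase, changed by -1.97 and -1.31 at its 2 probes. KHNYN, a cofactor of the antiviral protein ZAP, changed by -1.73 and ST6GALNAC6, a sialyltransferase, by -1.65. BTRC, the substrate receptor of an SCF ubiquitin ligase, was not detected on any of the 3 treated arrays and was at least 2.10-fold lower. SUMF1, which activates sulfatases, changed by -1.46, the Golgi protein gene GOLGA3 by -1.15 and NIPAL4 by -1.12. CRLF3, KHNYN and NIPAL4 were detected on 2 of the 3 treated arrays, so their changes depend on signal near the background. RPL13A, a ribosomal protein gene whose pseudogene copies the probe may not separate, changed by -1.04. The other genes that rose were CHPF, a chondroitin synthesis factor, at 1.67, CTDSP2, a phosphatase gene, at 1.51, and TOR1A, an ATPase of the endoplasmic reticulum, at 1.29. SFT2D2 rose by 1.10 at one probe, where its other probe read 0.50. SEC24C, a coat protein of vesicles leaving the endoplasmic reticulum, rose by 1.09, and the RNA polymerase III subunit POLR3E by 0.94. The adjusted p of these 20 named genes ran from 0.0107 (KRT80 and NIPAL4) to 0.0498 (AXL and TOR1A).

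With 11 arrays HTATIP2 had a log2 change of -1.06 ± 0.11 (SE) and an adjusted p of 4.14e-04. The largest falls were in CRLF3 (-2.15), CMPK1 (-1.90), the small GTPase gene RAP2A (-1.89), ISCA2, an assembly factor for mitochondrial iron-sulfur proteins (-1.82, detected on 1 of the 2 treated arrays), SUMF1 (-1.65) and the exocyst gene EXOC2 (-1.56). They were followed by ST6GALNAC6 (-1.53), LRRC8B (-1.49), the histone H3.3 gene H3-3B (-1.48, with near-identical copies elsewhere), BTRC (at least 2.36-fold lower), ZMYND11 (-1.39) and KHNYN (-1.36). The other probes of LRRC8B and ZMYND11 read -0.10 and -0.07. SDC1, the cell-surface proteoglycan syndecan-1 and a described miR-10b target, fell by 1.26 ± 0.15 (SE) with an adjusted p of 8.46e-04, while its other probe read 0.15 and the 12-array change was -0.98 with an adjusted p of 0.287. The largest rises were in AXL (2.15), CHPF (1.77), KRT80 (1.75), TOR1A (1.54), CTDSP2 (1.43), WBP1L (1.35), RRAGC, a GTPase of the amino acid signal to mTORC1 (1.33), and RDH11, a retinol dehydrogenase (1.31). SFT2D2 (1.17, other probe 0.05), NRBP1 (1.17), SSH1, a phosphatase of cofilin (1.11), and RNF167 (1.11) completed the 12 largest.

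**Figure D2:**
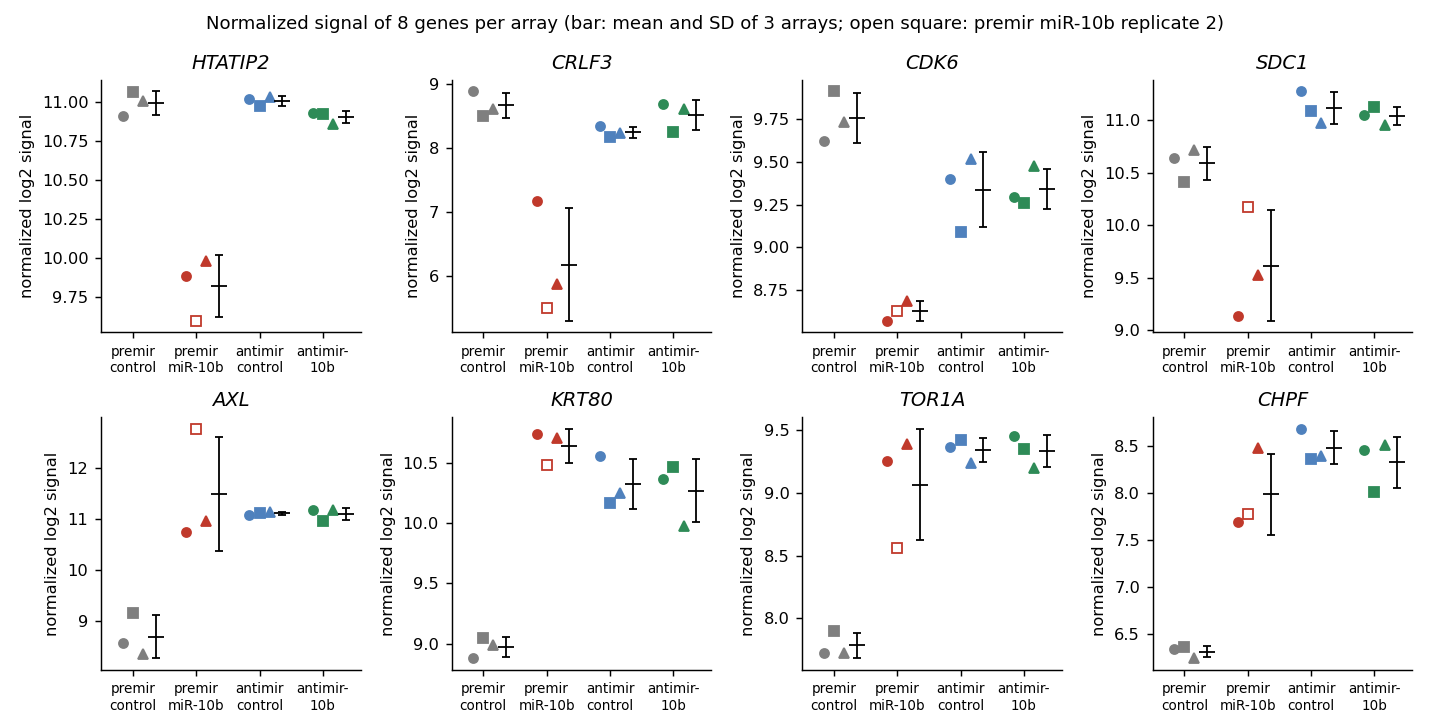
Normalized log2 signal of 8 genes on each of the 12 arrays, by group, with the mean and SD of the 3 arrays as a bar and premir miR-10b replicate 2 as an open square. HTATIP2, CRLF3, CDK6 and SDC1 lie lower after premir miR-10b than in the other 3 groups, and AXL, KRT80, TOR1A and CHPF lie lower in premir control than in the other 3 groups.

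Among the 29 gene lists, the named miR-10b targets moved down after premir miR-10b. Of its 35 measured members 3 fell with 12 arrays (HTATIP2, CRLF3 and BTRC), 0 rose and 32 were not called, and 7 fell when adjusted over the list alone. Its median log2 change was -0.34, with an adjusted camera p of 4.26e-04. Its adjusted p was 0.214 with an estimated correlation and 0.0347 with fry. The median was -0.17 without premir miR-10b replicate 3 and -0.12 without a filter. HTATIP2 was placed on the list because it is a known target in this kind of cell, so its fall is not independent evidence. With 11 arrays 6 members fell, adding SDC1, the cell cycle repressor E2F7 (-0.98) and WDR26 (-0.90), 0 rose, and 11 fell and 1 rose when adjusted over the list alone. The median was then -0.28, the adjusted camera p 4.35e-09 and the adjusted p 0.144 with an estimated correlation and 0.0253 with fry. That median was -0.09 without premir miR-10b replicate 3 and -0.17 with the values scaled by the authors or without a filter. The G2 and mitosis list shares BUB1, PLK1 and CCNA2 with the named targets, so the results of these lists are not independent. The G2 and mitosis list had a median of -0.26 over 32 measured members, 0 of them called by limma and 0 called when adjusted over the list alone. Its adjusted camera p was 0.00607 and its adjusted p 0.288 with an estimated correlation. With 11 arrays 28 of its 32 members were negative, the median was -0.20 and the adjusted camera p 3.99e-05. The adjusted p with an estimated correlation was then 0.466. Fry gave the G2 and mitosis list an adjusted p of 0.099 with 12 arrays and 0.195 with 11. Without premir miR-10b replicate 3 the adjusted camera p was 0.0765 and, in the 11-array analysis, 0.182 with a median of -0.10. Without replicate 1 the medians were -0.40 and -0.33, and the values scaled by the authors gave -0.56 with 12 arrays. The list was also lower in antimir control than in premir control, with a median of -0.21 and an adjusted p of 0.642 with an estimated correlation (0.97 with 11 arrays), and its mean on premir miR-10b replicate 1 (10.30) lay above those of the antimir control arrays (10.23 to 10.25). Its uncalled members with the smallest p included ANLN, which acts in cytokinesis (-1.05 with 12 arrays, -0.83 with 11), CDK1 (-0.80 with 12) and NUSAP1 (-0.44 with 11). The 11-array change of ANLN ran from -1.31 to -0.35 over the alternatives.

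Mitochondrial respiration (31 measured, 0 called, 0 adjusted over the list alone) and heat shock and oxidative stress (21 measured, 0 called, 1 lower adjusted over the list alone) had medians of -0.38 and -0.31 with 12 arrays. Their adjusted camera p values were 0.0197 and 0.0493, and 0.609 and 0.288 with an estimated correlation. Fry gave adjusted p values of 0.421 and 0.19. Without premir miR-10b replicate 2 the medians were -0.01 and -0.10 and the adjusted camera p values 0.629 and 0.129. With the values scaled by the authors the medians were -0.66 and -0.45 and the adjusted p values 0.326 and 0.161, and that of the stress list was 0.0765 to 0.144 without premir control replicate 2 or premir miR-10b replicate 1 or 3. In the respiration list CYCS, cytochrome c, had a change of -0.93 and NDUFB10, a complex I subunit, of 0.53, both uncalled. In the stress list GCLM, a subunit of the enzyme that limits glutathione synthesis, had -1.15 with 12 arrays, uncalled, and fell by 0.78 with 11 arrays, while GCLC had -0.41 with 12, uncalled. The lists for the EGF receptor pathway (median -0.11, adjusted camera p 0.583), ERK output (0.19, 0.674), TGF-beta (-0.06, 0.74), the epithelial state (-0.26, 0.0511), the mesenchymal state (0.26, 0.253, with AXL as its called member) and invasion (0.03, 0.767) did not pass the threshold with 12 arrays. With 11 arrays their medians were 0.03, 0.18, 0.03, 0.02, 0.07 and -0.12 and their adjusted camera p values 0.629, 0.129, 0.514, 0.665, 0.192 and 0.218. Of the genes fixed by name, KLF4 (-0.44, other probe -1.32), NF1 (0.12), TIAM1 (-0.22), BDNF (not detected in premir control, value at least 1.02-fold higher), BCL2L11 (0.35), HOXB3 (-1.05, other probe 0.39), EGFR (-0.08, other probes 0.40 and 0.50), CDH1 (-0.26) and VIM (-1.12, other probe -0.82) were not called with 12 arrays. With 11 arrays the changes of KLF4, NF1, TIAM1, BCL2L11, HOXB3, EGFR, CDH1 and VIM were -0.28, 0.05, -0.16, 0.14, -0.38, 0.00, -0.03 and -0.09 and BDNF was at least 1.04-fold higher, again uncalled. On the 3 premir miR-10b arrays HOXB3 and NF1 were detected on 2, and TIAM1 and CDH1 on 1. HOXD10 and ZEB1 were detected in 1 and 0 arrays, and HOXA3 had no probe under that symbol. The 22 calls became 0 without any one premir control array or with the 6 compared arrays alone, 67 and 7 without premir miR-10b replicates 1 and 3, 6 to 13 without antimir control replicate 2 or 3 or any one antimir-10b array, 2 with median centring and 1023 with array weights. The weights of premir miR-10b replicates 1, 2 and 3 were 0.36, 0.027 and 2.53, so the 1023 calls rest largely on replicate 3. The 124 calls became 75 without premir control replicate 3, 367 and 71 without premir miR-10b replicates 1 and 3, and 42 with the values scaled by the authors.

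**Figure D3:**
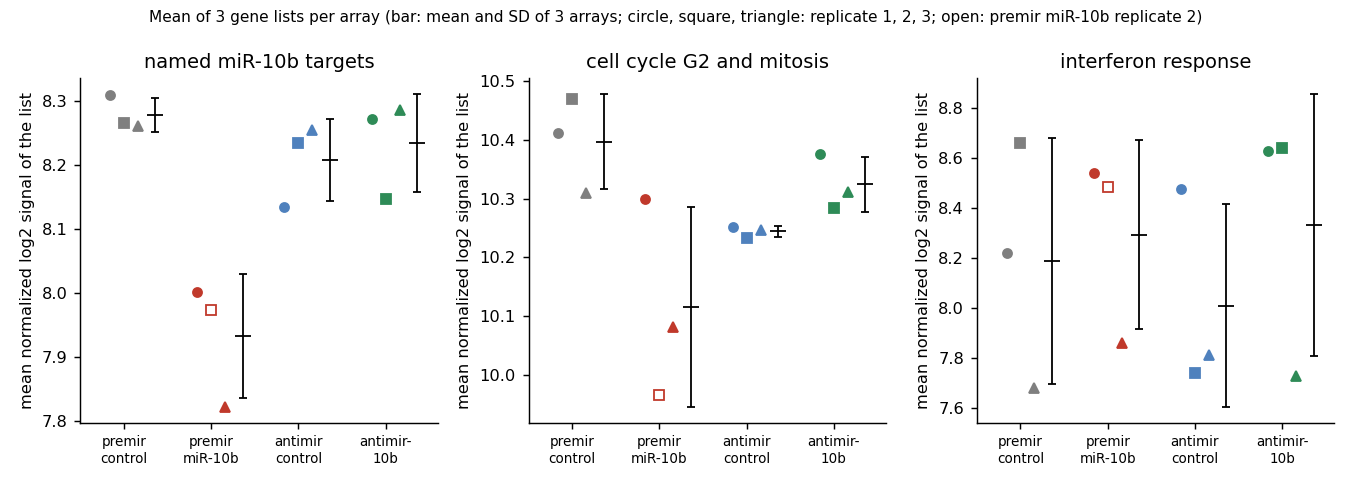
Mean normalized log2 signal of the measured members of 3 gene lists on each of the 12 arrays, by group, with the mean and SD of 3 arrays as a bar. The named miR-10b targets lie lower on the 3 premir miR-10b arrays than on the 9 others, and the interferon list spans 0.68 to 0.98 log2 units within each group.

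The comparison of antimir-10b with antimir control asks which transcripts change when miR-10b is inhibited. HTATIP2 had a log2 change of -0.10, with a 95% interval from -0.39 to 0.18 with 12 arrays and from -0.32 to 0.11 with 11, so a rise of the size of its fall after premir miR-10b lies outside both. SDC1 had -0.07, KLF4, a transcription factor described as a miR-10b target, 0.24, and the homeobox gene HOXB3 0.45 (other probe 0.02). EGFR, the epithelial adhesion gene CDH1 and the mesenchymal filament gene VIM had 0.12 (other probes -0.08 and 0.22), 0.29 and 0.07 (other probe -0.11), and NF1, TIAM1 and BCL2L11 had 0.07, -0.03 and 0.16. BDNF was not detected in antimir-10b, with a value at least 1.04-fold lower, uncalled. By limma 0 of 17369 features were called with 12 arrays and 0 with 11, where 46 and 365 had an unadjusted p under 0.05 and 868 would by chance. The smallest p values with 12 arrays belonged on the positive side to CBFA2T2 (0.48), TMEM60 (0.31), PLEKHA7, SPIN2B and LNX2 (0.45), and on the negative side to NSMCE3 (-0.48), NIPAL4 (-0.35), TOR3A (-0.57), MAGEA1 and ITPRIPL1 (-0.40). With 11 arrays GALNT4 (0.42), CES4A (0.37), SETD6 (0.46), ANKRD23 (0.37), the cell cycle regulator E2F1 (-0.61), DNAJB5 (-0.58), ANAPC2 (-0.56) and FMNL1 (-0.44) joined CBFA2T2 and NSMCE3. PLEKHA7 and SPIN2B were not detected in antimir control, with values at least 1.18-fold and 1.05-fold higher in antimir-10b, and MAGEA1 was not detected in antimir-10b, with a value at least 1.04-fold lower.

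The interferon response list had 30 of 33 measured members positive after antimir-10b, 0 called and 0 adjusted over the list alone, with a median log2 change of 0.34. Its adjusted camera p was 1.08e-07 with 12 arrays and 1.24e-05 with 11, and the adjusted p with an estimated correlation was 0.647 and 0.642. Fry gave the list adjusted p values of 0.974 and 0.747. IFIT5 (0.51) and IFI27 (0.42), both induced by interferon, had its smallest p values and were not called. The list's mean differed between replicates of antimir-10b by 0.91 log2 units, and leaving antimir-10b replicate 2 out of the 12 arrays gave an adjusted camera p of 0.117. Its median ran from 0.19 without that array and 0.20 without antimir-10b replicate 1 to 0.62 without antimir-10b replicate 3, and was 0.57 and 0.21 without antimir control replicates 1 and 3. In the 11-array analysis the adjusted camera p missed the threshold, at 0.0665 to 0.194, without any one of antimir control replicates 2 and 3 and antimir-10b replicates 1 and 2. The named miR-10b targets had a median of 0.06, with 23 of 35 members positive, 0 called and an adjusted camera p of 0.591 with 12 arrays and 0.465 with 11. The G2 and mitosis list (median 0.09, 0 called) had an adjusted camera p of 0.0991 with 12 arrays and 0.0455 with 11, and an adjusted p of 0.642 with an estimated correlation in the latter, where the adjusted camera p was 0.0532 to 0.248 without premir control replicate 1 or 2 or any one of the 4 antimir-arm arrays just named. Its median with 11 arrays was 0.04 and 0.14 without antimir-10b replicates 1 and 2 and 0.21 with the values scaled by the authors. Its members CENPA, the centromeric histone, and NUSAP1 had 0.22 and 0.20, uncalled.

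The difference between the premir and antimir effects asks which genes respond differently to adding and to inhibiting miR-10b. With 12 arrays limma called 0 genes (569 at an unadjusted p under 0.05, 868 by chance). With 11 arrays it called 63, of which 18 were more positive after premir miR-10b and 45 more negative. The most positive differences were in AXL (2.16), CHPF (1.93), KRT80 (1.81), WBP1L (1.66) and CTDSP2 (1.59), and the most negative in CRLF3 (-2.42), CMPK1 (-2.35), ISCA2 (-2.02), RAP2A (-1.97) and LRRC8B (-1.80, other probe -0.10). In each of these the antimir effect alone was not called, and 0 genes were called in both comparisons in opposite directions. Across the 17369 features the effects had a Pearson correlation of -0.072 and a Spearman correlation of -0.085 with 12 arrays, with 46.8% of the signs equal, and of -0.135 and -0.127 with 11 arrays, with 45.7% equal. These correlations are across genes, which are not independent replicates, and the Pearson value turned to 0.243 without premir miR-10b replicate 3 with 11 arrays and to 0.06 without antimir control replicate 1 with 12. The 63 calls became 275 and 35 without premir miR-10b replicates 1 and 3, 17 and 35 without antimir control replicates 2 and 3, 33 without antimir-10b replicate 1, and 30 to 37 without any one premir control array.

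The comparison of the antimir control with the premir control asks how far the control oligos themselves differ. CHPF was 4.48-fold higher in antimir control, TOR1A 2.95-fold, KRT80 2.55-fold and the vesicle coat gene SEC24C 2.54-fold, and these 4 genes were all that limma called with 12 arrays (352 at an unadjusted p under 0.05). That fit draws its spread partly from premir miR-10b replicate 2, which is not compared here (median SE 0.246, and 0.139 with 11 arrays). With the 6 compared arrays alone 112 features were called, 62 higher and 50 lower in antimir control. With 11 arrays 36 were called, 30 higher and 6 lower in antimir control. AXL had the largest difference, 2.42 ± 0.17 (SE) on the log2 scale with an adjusted p of 2.77e-05, from 8.69 ± 0.42 (SD, n = 3) in premir control to 11.11 ± 0.03 (SD, n = 3) in antimir control. WBP1L had 1.56. The genes lower in antimir control included ANKRD52 (-0.87), KCTD20 (-0.83), BBOF1 (-0.73), MATCAP2 (-0.66) and MTMR9 (-0.62). The S phase list was higher in antimir control (median 0.20, 1 of 28 measured members called with 11 arrays, the DNA methylation factor UHRF1, and 2 adjusted over the list alone) and the G2 and mitosis list lower (median -0.21, 0 called). Their adjusted camera p values were 9.32e-04 and 0.00626 with 11 arrays and both 0.0221 with 12, and with an estimated correlation the adjusted p was 0.806 and 0.97 with 11 arrays and 0.174 and 0.642 with 12. The 4 calls became 0 without any one premir control or antimir control array or antimir-10b replicate 1 and 2 without antimir-10b replicate 2 or premir miR-10b replicate 1, and the 36 became 9 to 23 without any one of these 6 arrays and 91 without either remaining premir miR-10b array.

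Of the 40 features that rose after premir miR-10b with 11 arrays, 22 were also among the 30 that were higher in antimir control than in premir control, where 0.0691 would overlap if the lists were independent. They are not, since both comparisons use the same 3 premir control arrays. Across the 17369 features the changes of these comparisons had a covariance of 0.0231 and a correlation of 0.482. In 100 simulations with no effect in either, the shared arrays alone gave a mean covariance of 0.0119 (at most 0.0126), a mean correlation of 0.446 (at most 0.465) and at most 1 feature called higher in both (mean 0.01). The simulated noise was drawn separately for each feature, so these maxima lack variation shared between features. With no effect few features are called at all, so the simulated count cannot tell how much of the overlap of 22 comes from the shared arrays. Against the 6 arrays of the antimir arm, a comparison group chosen after the data were seen, the 84 features that fell had a median log2 change of -0.94 (-0.99 against premir control), 83 had the same sign and 60 were called. The same 2 treated arrays enter both comparisons, so noise on them would be kept in either. The exception in sign was KCTD20 at 0.02. HTATIP2 had -1.02 (adjusted p 1.76e-04), SDC1 -1.75 (5.65e-05), CRLF3 -1.86, CMPK1 -1.94 and CDK6 -0.71 (0.0263) against these arrays. Of the other named miR-10b targets that fell, BTRC was called (-1.24), while E2F7 (-0.43, adjusted p 0.317) and WDR26 (-0.60, 0.154) were not. The 40 that rose had a median of 0.25 (0.92 against premir control), 30 had the same sign and 1 was called, the zinc finger gene ZNF286A at 0.71, named here after its value was seen. AXL had -0.26 (adjusted p 0.717), KRT80 0.43 (0.295), CHPF -0.31, TOR1A -0.02 and RRAGC -0.01 against the antimir arm.

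**Figure D4:**
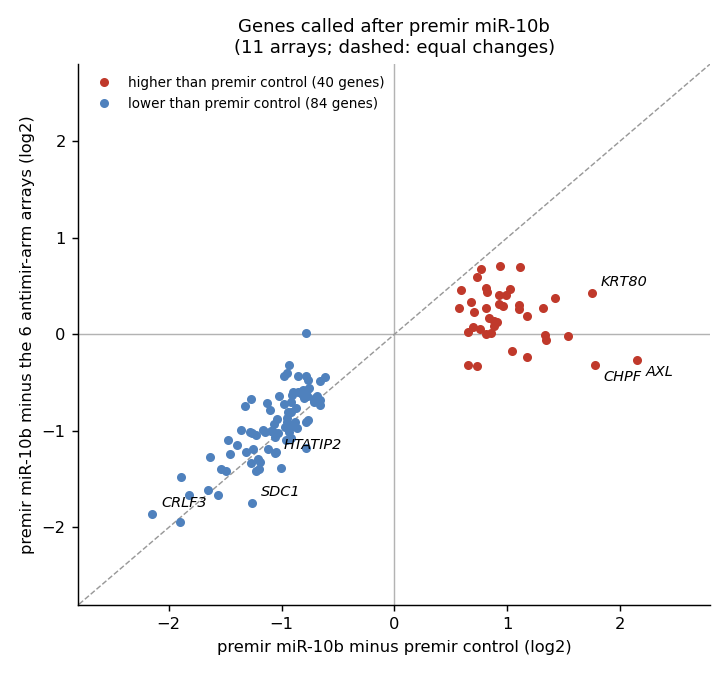
Each point is a feature called after premir miR-10b with 11 arrays, with its log2 change against premir control on the x axis and against the 6 antimir-arm arrays on the y axis, and the dashed line marks equal changes. The 84 that fell lie near the line, with medians of -0.99 and -0.94, and the 40 that rose lie below it, with medians of 0.92 and 0.25.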

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

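The tests of premir miR-10b replicate 2, of the genes that rose, and of a release of the fallen genes and of the precursor's level after antimir-10b were chosen or given their bounds after the results were seen; the test of array noise in the antimir arm and the counts of other splits were planned.

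With 11 arrays the premir and antimir effects differed for 63 genes by limma's test of the difference itself. The difference was 2.16 ± 0.26 (SE, adjusted p 0.00285) in AXL, 1.93 ± 0.28 (0.0117) in CHPF, 1.81 ± 0.22 (0.00285) in KRT80, 1.66 ± 0.31 (0.0343) in WBP1L and 1.59 ± 0.25 (0.0148) in CTDSP2. It was -2.42 ± 0.37 (0.0139) in CRLF3, -2.35 ± 0.36 (0.0139) in CMPK1, -2.02 ± 0.21 (0.00264) in ISCA2, -1.97 ± 0.30 (0.0139) in RAP2A and -1.80 ± 0.22 (0.00285) in LRRC8B. The named genes with a positive difference were also called higher in antimir control than in premir control, and none was called against the antimir-arm arrays. With 12 arrays limma called 0 genes in this difference, with 569 at an unadjusted p under 0.05. There 100 of 100 drawn splits of both arms called at least as many, the highest other split 1, which a count of 0 makes certain, so that this says nothing about chance. Of the 10 genes named, 3 were called under every alternative run, and 31 of 229 alternative fits ended a call, 14 of them for WBP1L out of 23.

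Many of the 40 features higher after premir miR-10b than in premir control, AXL, CHPF and TOR1A among them, lay near their level in both antimir groups. Others had higher values, such as KRT80 (0.43 higher, not called) and ZNF286A (0.71 higher, called). Noise that differs from one premir control array to the next is argued against under the bound used. Genes picked with 1 premir control array kept a median gap of at least 0.432 (log2) on the other 2. The upper limit of expression-matched random lists was at most 0.099. An earlier bound of 0.5 on this gap was not reached and was replaced after the value was seen. Under that earlier bound the question would have stayed undecided. A shift common to all premir control arrays would leave the same gap, so this test cannot address it. A lowering of these genes by the premir control oligo and a raising by miR-10b both stay open, since the median difference of premir miR-10b from the antimir arm was 0.248, or 27.1% of the median rise, between the bounds set for either. A control oligo with targets of its own may account for part of the 40 rises. These data cannot tell it from a shift common to all premir control arrays.

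The 84 features that fell after premir miR-10b had a median log2 change of 0.0818 after antimir-10b, with 61 of 84 positive, above the matched random lists (-0.035 to 0.042). A release of these genes by the inhibitor stays open, because another split of the same 6 arrays gave a median of 0.0816. That same 0.0816 is under 0.248, the bound set from the size of the fall, which argues against array noise hiding a release as large as that bound. Little miR-10b to inhibit in these cells also stays open: the probe of its precursor was detected in 0 of the 3 antimir control arrays, which the low level of any precursor would give too.

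Premir miR-10b replicate 2 differed from the other arrays in more than brightness: the SD of its log2 ratio over bright probes was 5.19 times the largest of the other 11. A missing response to miR-10b is argued against, since the genes that fell on replicates 1 and 3 had a median of -0.598 on this array relative to the 6 antimir-arm arrays, which did not pick them, below the matched random lists (-0.462 to 0.537). The deviations of 2 probes of the same gene were uncorrelated on it, at -0.007 over 787 genes, against 0.370 to 0.727 on the other arrays. A failure in RNA, labelling or hybridisation that differs from probe to probe is a candidate explanation, and the step is not named by this test. Apart from the response to miR-10b, no biological explanation was tested for this array.

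For the 22 genes called after premir miR-10b with 12 arrays, 1 of the 10 splits of the 6 arrays gave as many, the highest other split 1. For antimir-10b the real count was 0 and the highest other split 0, so that 10 of 10 gave at least as many by necessity. For the control oligos 1 of 10 gave at least 4, the highest other split 0. With 10 splits a share under 0.05 cannot be reached. For the correlation of -0.072 between the effects, 69 of 100 splits gave one as large, the highest other 0.297, so chance cannot be excluded.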

How the results depend on the processing

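The 11-array results with all their alternatives, and the comparisons with the 6 antimir-arm arrays, were chosen after the data were seen; the other alternatives were planned. The causes of the changes below were not tested, except where the construction of a fit gives them. A fold minimum makes a test stricter by construction. All comparisons share 1 estimate of spread. Leaving out premir miR-10b replicate 2 therefore changes only that spread for the antimir and control-oligo comparisons, whose own arrays stay the same. Their median SE was 0.246 with 12 arrays and 0.139 with 11. For premir miR-10b the 22 calls (8 higher, 14 lower) became 8 with the authors' values (2 and 6, 3 of them shared), 2 with median centring (0 and 2), 13 with detection in all arrays (6 and 7), 0 with the replicate block, 8 with trend and robust variances (2 and 6), 1023 with array weights (433 and 590), 3 with a fold minimum of 1.2, 0 with only the compared arrays, 21 against the 6 antimir-arm arrays (0 and 21), and 0 to 124 leaving out 1 array. The 0 counts are limma's, beside 1471 at an unadjusted p under 0.05 with all 12 arrays. With 11 arrays the 124 calls (40 and 84) became 42 with the authors' values (12 and 30), 52 with median centring (26 and 26), 72 with array weights, 55 with the fold minimum (13 and 42), 71 with only the compared arrays, 105 against the 6 antimir-arm arrays (11 and 94), and 71 to 367 leaving out 1 array, where a lone treated array is assumed to vary like the other groups. No alternative called a gene after antimir-10b. With 12 arrays the weights of premir miR-10b replicates 1, 2 and 3 were 0.36, 0.027 and 2.53. Weighted counts that use this group thus rest largely on replicate 3. The difference moved from 0 to 638 with array weights (255 and 383) and 0 to 63 leaving out 1 array. With 11 arrays it moved from 63 (18 and 45) to 18 with the authors' values (7 and 11), 14 with median centring (8 and 6), 35 without a filter, 36 with the replicate block, 24 with the fold minimum and 17 to 275 leaving out 1 array. For the control oligos the 4 calls became 0 with the authors' values, median centring or the replicate block, 1 with trend and robust variances or the fold minimum, 147 with array weights (90 and 57), 112 with only the compared arrays (62 and 50), and 0 to 36 leaving out 1 array. With 11 arrays the 36 (30 and 6) became 16 with the authors' values (16 and 0), 21 with median centring (21 and 0), 147 with array weights, 9 with the fold minimum (9 and 0), 112 with only the compared arrays, 82 for the 6 antimir-arm arrays (63 and 19) and 9 to 91 leaving out 1 array. The 4 lists past the threshold after premir miR-10b became 0 with an estimated correlation, 1 with fry and 2 to 5 leaving out 1 array; with 11 arrays the 2 became 4 without a filter, 0 with an estimated correlation, 1 with fry and 2 to 4 leaving out 1 array. The 1 list after antimir-10b became 3 with the authors' values, 0 with an estimated correlation or fry and 0 to 5 leaving out 1 array; with 11 arrays the 2 became 5 with the authors' values, 4 with the replicate block or without a filter, 0 with an estimated correlation or fry and 0 to 6 leaving out 1 array. The correlation of -0.072 became -0.246 with the authors' values, -0.15 with median centring, -0.295 over called genes and -0.137 to 0.06 leaving out 1 array, turning to 0.01 without premir miR-10b replicate 3 and 0.06 without antimir control replicate 1. With 11 arrays the -0.135 became -0.332 over called genes and -0.358 to 0.243 leaving out 1 array, turning to 0.243 and 0.012 without the same arrays. Replicate numbers were not taken to pair the arrays, since not all same-numbered arrays deviated together: their correlations were 0.208, 0.029 and 0.06 in the premir arm (0.419 and 0.19 for numbers 1 and 3 with 11 arrays), 0.16, -0.102 and 0.364 in the antimir arm and -0.09, -0.182 and 0.091 between the controls, and not every array correlated best with its own number. Some lists did share a pattern by number, seen after the results: cholesterol synthesis had its lowest mean on replicate 3 in all 4 groups (8.68, 8.71, 8.80 and 8.76). A shared state of same-numbered arrays is thus not excluded. The replicate block gave 101 calls after premir miR-10b with 11 arrays. Normalization of the 11 arrays alone gave 122 calls, all shared with the 124. For the 20 named genes called with 12 arrays, 251 of 475 alternative fits ended a call and 0 turned its direction; for the 26 called with 11 arrays, 23 of 621 did and 18 genes were called in every fit run. HTATIP2 kept its call in all 24 alternatives with 11 arrays (adjusted p 1.23e-04 to 0.0202) and lost it in 8 of 24 with 12 (adjusted p up to 0.718). For the named genes called between the control oligos, 55 of 96 alternative fits ended a call with 12 arrays and 60 of 239 with 11, where 4 of 10 genes were called in every fit run. Signal over background limits genes undetected in a compared group (BTRC, BDNF, PLEKHA7, SPIN2B, MAGEA1) or on some of its arrays (ISCA2, CRLF3, KHNYN, NIPAL4, HOXB3, NF1, CYCS, TIAM1, CDH1 among those named). Seed sites, a slide block, and only the compared arrays for the difference were not run.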

Other observations

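The interferon values per array and the single genes below were looked at after the results were seen, while the list tests were planned. The interferon response list, which holds IFIT1, MX1, OAS1 and other genes induced by interferon, varied more between replicates than between groups. Its mean normalized log2 signal was 8.22, 8.66 and 7.68 in the 3 premir control arrays, 8.54, 8.48 and 7.86 in premir miR-10b, 8.48, 7.74 and 7.81 in antimir control and 8.63, 8.64 and 7.73 in antimir-10b. The spread within a group was 0.98, 0.68, 0.74 and 0.91 log2 units in that order, while the 4 group means lay between 8.01 and 8.33. Replicate 3 lay low in all 4 groups, and antimir control replicate 2 lay as low. Taken by number, the antimir arm went from 7.74 to 8.64 for replicate 2, but from 8.48 to 8.63 for replicate 1 and from 7.81 to 7.73 for replicate 3.

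With 11 arrays a few members of lists that did not pass the threshold were called after premir miR-10b. EDEM1, which acts in the disposal of misfolded proteins, fell by 1.196 on the log2 scale (adjusted p 4.59e-04). The chemokine gene CXCL1 rose by 0.93 (adjusted p 0.0114) and was also 0.79 higher in antimir control than in premir control (adjusted p 0.0389). UHRF1 rose by 0.65 (adjusted p 0.0327) and was 0.97 higher in antimir control (adjusted p 0.00267). E2F1, by contrast, is on the named miR-10b targets list, which moved down, as well as on the S phase list. It was uncalled in both single comparisons, with a change of 0.59 after premir miR-10b (adjusted p 0.2) and -0.61 after antimir-10b (adjusted p 0.999). The difference of 1.21 was called (adjusted p 0.0363), in the direction opposite to that of its target list.

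These lists did not pass the threshold after premir miR-10b with 12 arrays. After premir miR-10b the median log2 change and adjusted camera p were 0.12 and 0.583 for S phase, -0.10 and 0.583 for p53 targets, 0.22 and 0.854 for interferon response, 0.08 and 0.948 for NF-kB and inflammatory cytokines, 0.19 and 0.767 for cholesterol synthesis, 0.16 and 0.767 for fatty acid and lipid synthesis, and 0.00 and 0.583 for the unfolded protein and amino acid response. They were -0.39 and 0.0731 for hypoxia and glycolysis, -0.23 and 0.853 for metallothioneins, 0.17 and 0.171 for HOX genes, 0.16 and 0.573 for small RNA machinery, -0.13 and 0.254 for replication-dependent histones, -0.40 and 0.0731 for ribosomal proteins, and -0.01 and 0.854 for apoptosis. Markers of other cell types had medians of 0.42 (5 fibroblast genes measured, adjusted camera p 0.342), 0.41 (7 leukocyte genes, 0.0711), -0.17 (2 endothelial genes, 0.853), -0.17 (4 acinar and islet genes, 0.583) and -0.27 (7 ductal genes, 0.853). Several of these values came largely from premir miR-10b replicate 2: its list mean was 11.6 for ribosomal proteins (12.5 on both other treated arrays), 9.39 for hypoxia and glycolysis (9.97 and 10.04), 7.64 for leukocyte markers (6.58 and 6.65) and 8.25 for fibroblast markers (7.37 and 7.52). With 11 arrays the medians of these 4 lists were 0.01, -0.10, 0.10 and 0.05, with adjusted camera p values of 0.969, 0.192, 0.209 and 0.629. After antimir-10b the smallest adjusted camera p among the lists not past the threshold was 0.0644, for NF-kB and inflammatory cytokines (median -0.07) and for replication-dependent histones (median 0.12).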
